A study of Glycine max with 18 samples.

How the data were processed

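Root RNA of soybean (Glycine max) was measured by RNA-seq in 18 libraries, 6 groups of 3. The groups are the cultivar Williams 82 and its lines WT-GmBIR1 and KD-GmBIR1, each noninfected or infected with the soybean cyst nematode Heterodera glycines HG type 0. Per the labels, RNA was extracted with hot phenol, enriched for poly(A) RNA and sequenced in read pairs. The sources used here do not expand KD. The titles call the libraries of a group biological replicates without naming plants, so the p-values measure the spread between these libraries.

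The authors deposited 1 table of whole-number read counts per gene, not normalized. Per the submitters' processing notes, the tools were Trimmomatic, STAR, HTSeq and DESeq2, and their versions and the roles of the tools are not given in the sources used here. Each column name is the description of 1 sample, and the table holds 52872 gene IDs of the Wm82.a4.v1 annotation and 5 HTSeq summary rows. The summary rows stayed out of library sizes and tests. They made up 5.43% to 8.44% of all counted alignments in 17 libraries and 75.1% in Williams 82 noninfected replicate 3. Gene counts summed to between 44065636 and 96798188 per library. Whether strand was used in counting is not given, so overlapping and antisense genes are uncertain. Reads with several alignments were counted apart, in a summary row, so near-identical copies of a gene may be under-counted, and the values of the related alpha-SNAP genes Glyma.18G022500 and Glyma.11G234500 are uncertain to that extent.

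From the counts, genes were kept by filterByExpr on the 6 groups (42965 of 52872), libraries were scaled by TMM, and all 18 libraries were fitted in 1 model of the 6 groups with edgeR 4.0.16 in R 4.3.3 (robust quasi-likelihood fit and test, two-sided, Benjamini-Hochberg adjustment, threshold 0.05). A gene is called when its adjusted p passes that threshold. The 12 comparisons are the infection response of each of 3 genotypes, each line against Williams 82 in either state, WT-GmBIR1 against KD-GmBIR1 in either state, and the 3 differences between infection responses (interaction contrasts). Standard errors are those implied by the test. CPM values are TMM-scaled, and principal components used log2 CPM with a prior count of 2.

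The reference table of 59048 genes carries no ID of this annotation, and 0 of the 52872 IDs matched it. The 30 lists fixed as name patterns before the data were examined, the BIR1 annotated genes and the cell type markers could therefore not be read, and the transgene could not be used to check the labels. The 5 cyst nematode resistance locus genes had been fixed by ID. Their names come from published work on those IDs and are not paired with them in the files, and whether the IDs stand for the same genes in Wm82.a4.v1 was not checked. The rule for named genes took, per comparison, called genes with an absolute log2 fold change of at least 1, a mean of at least 5 CPM in the higher group and, between 2 groups, no overlap of libraries. Of these the 2 with the largest rise and the 2 with the largest fall were named, since no gene names were given. The 5 list genes were named in all comparisons. Where a group held 0 counts, a fold is a lower bound against 3 counts per library. Such bounds cover counting error only and take each count as 1 molecule. They would be lower if each molecule was counted several times.

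The fit was tested on simulated data with 200 changed genes per infection comparison among 42965. With equal spread, the 18-library fit recovered 55%, 63% and 56% of 4-fold changes in Williams 82, WT-GmBIR1 and KD-GmBIR1, with 2, 6 and 1 false calls among 67, 74 and 68, and a fit of only the 2 groups made 2, 12 and 1 false calls among 45, 69 and 44. The real groups differ in spread, with a biological coefficient of variation of 1.14 in Williams 82 noninfected and 0.176 to 0.595 in the other groups. With those spreads, the 18-library fit made 2416 false calls among 2520 in Williams 82, 0 among 64 in WT-GmBIR1 and 13 among 63 in KD-GmBIR1. It recovered 71%, 56% and 44% of 4-fold changes. A fit of only the 2 groups made 0 calls in Williams 82. In WT-GmBIR1 it made 171 calls, 17 of them false, and in KD-GmBIR1 80, 15 of them false, and it recovered 92% and 59% of 4-fold changes. The pass mark of this test was limited to the equal-spread 18-library case after the unequal case had failed it. The count from the fit of only the groups compared is printed beside each count for this reason.

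Alternatives fixed before the data were examined were DESeq2 1.42.0 size factors, its Wald test, no filter, a replicate block, a fit of only the groups compared and leaving out each replicate. Added after the data were seen were voom with quality weights per group (limma 3.58.1), leaving Williams 82 noninfected replicate 3 out of the shared spread, and counts divided by the modal low count of their library. That divisor was defined a second time, as the most common even low count, after the calls of the first definition were seen, because many values of the first lay at the edge of its range, and both are reported. Overlaps against the shared Williams 82 libraries were set beside 12 simulations of unchanged groups. Set tests on the pattern lists were not run.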

Results

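The study asked how roots of Williams 82 soybean, and of lines overexpressing the immune receptor construct WT-GmBIR1 or KD-GmBIR1, respond to the soybean cyst nematode. Each of the 6 groups held 3 libraries with totals of 44065636 to 96798188 gene counts, in which 34497 to 48924 genes were detected. Libraries of WT-GmBIR1 and of infected Williams 82 correlated within their groups at 0.988 to 0.993 (Spearman, across genes, which are not independent replicates). Libraries of Williams 82 noninfected correlated at 0.818 to 0.967, KD-GmBIR1 noninfected at 0.964 to 0.989 and KD-GmBIR1 infected at 0.953 to 0.967. The mean correlation of Williams 82 noninfected with the other groups was 0.763 to 0.85, and the other groups correlated with each other at 0.859 to 0.964.

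**Figure D1:**
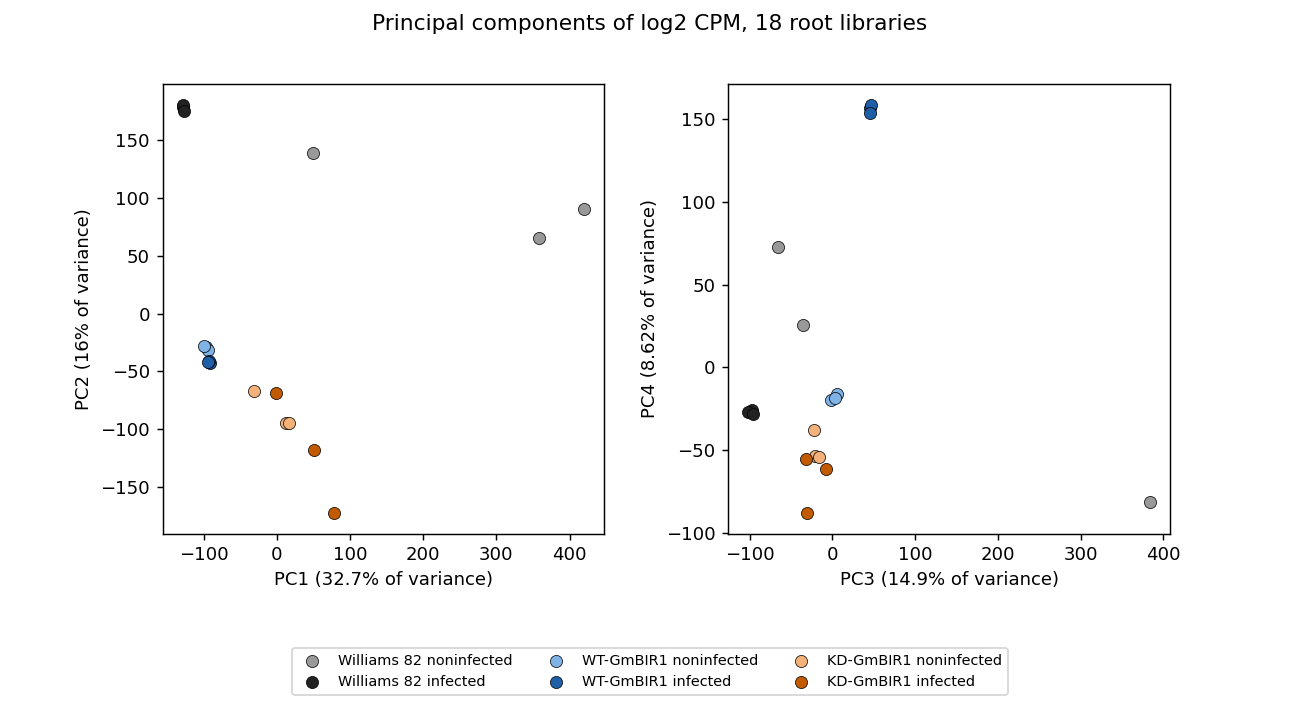
Principal components 1 to 4 of log2 CPM, each point 1 library coloured by group, with the share of variance on the axes. Replicates 1 and 2 of Williams 82 noninfected lie at 358.6 and 420.2 on the first component, and replicate 3 lies at 383.7 on the third.

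The genes at the resistance loci Rhg1 and Rhg4, which determine resistance to this nematode in other cultivars, were read first because they had been fixed by ID. Their names come from published work, since the files do not pair IDs with names, and whether the IDs stand for the same genes in the annotation Wm82.a4.v1 was not checked, so the names are provisional. The Rhg1 locus on chromosome 18 holds an amino acid transporter (Glyma.18G022400), an alpha-SNAP of vesicle fusion (Glyma.18G022500) and a wound-inducible WI12 protein (Glyma.18G022700). Rhg4 on chromosome 8 is a serine hydroxymethyltransferase of folate metabolism (Glyma.08G108900), and Glyma.11G234500 is an alpha-SNAP on chromosome 11.

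Infection of Williams 82 was accompanied by lower Rhg1 transporter and WI12 transcripts and a higher Rhg4 transcript. Glyma.18G022400 fell from 145 ± 34.5 to 46.9 ± 5.1 CPM (SD, n = 3; log2 fold change -1.63, SE 0.166, edgeR adjusted p = 8.34e-07). Glyma.18G022700 fell from 147 ± 85.1 to 31.1 ± 1.64 CPM (log2 fold change -2.24, SE 0.323, adjusted p = 2.97e-05). Its noninfected mean was raised by replicate 3, at 245.2 CPM against 102.9 and 92.97 CPM in replicates 1 and 2. Glyma.08G108900 rose from 54.1 ± 10.7 to 411 ± 26 CPM (log2 fold change 2.92, SE 0.257, adjusted p = 1.94e-07). Of the 5 list genes 3 were called over all genes and 3 adjusted over the list alone, and Glyma.18G022500 and Glyma.11G234500 did not pass (adjusted p = 0.101 and 0.501). Without Williams 82 noninfected replicate 3 Glyma.18G022500 passed (adjusted p = 0.00751, over all alternatives 0.00751 to 0.396). Among all genes, Glyma.14G032000 stood at 17 ± 2.37 CPM in infected roots and 0 counts in noninfected roots, at least 282-fold higher, and Glyma.15G062800 was at least 14200-fold lower. These and the other bounds take each count as 1 molecule, and would be lower if each molecule was counted several times. Even numbers were favoured among low counts in 17 of the 18 libraries. In all, 20511 of 42965 genes were called, 9648 higher and 10863 lower, and 12305 in the fit of only these groups. In data simulated with the spread of these groups and 200 changed genes, the 18-library fit made 2416 false calls among 2520 for this comparison. The fit of only these groups made 0 calls. The share of false calls depends on the number of changed genes, so the share in the real data is not known. The median log2 fold change of all genes was -0.16, and 1 noninfected library (replicate 3) held 68.7% non-unique alignments. Noninfected replicates 1 and 2 also differed from the rest, with TMM factors of 0.6955 and 0.7435 against 0.9591 to 1.133 in all other libraries. The whole reference group was thus unlike the other groups, and the changes by infection cannot be told apart from that.

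In infected WT-GmBIR1 roots the Rhg1 alpha-SNAP and WI12 genes were higher than in noninfected roots. Glyma.18G022500 rose from 134 ± 5.48 to 251 ± 3.44 CPM (SD, n = 3; log2 fold change 0.90, SE 0.133, edgeR adjusted p = 0.000429), and Glyma.18G022700 from 63.2 ± 3.1 to 266 ± 3.56 CPM (log2 fold change 2.08, SE 0.321, adjusted p = 0.000651). These were the 2 list genes called over all genes, and 4 were called adjusted over the list alone. Glyma.18G022400 was at 164 ± 0.283 CPM in noninfected and 238 ± 3.35 CPM in infected roots (adjusted p = 0.053, over the alternatives 3.23e-09 to 0.162). Glyma.11G234500 was at 46.6 ± 1.35 and 27.9 ± 1.77 CPM (adjusted p = 0.124, over the alternatives 1.3e-07 to 0.332). Both passed in the fit of only these groups, as did Glyma.08G108900 at 183 ± 2.92 and 203 ± 9.53 CPM (adjusted p = 0.842, over the alternatives 0.00917 to 0.957). Glyma.14G136351, with 0 counts in noninfected roots, was at least 749-fold higher (adjusted p = 0.0439), a call lost without any 1 of the 6 libraries (over the alternatives 3.09e-17 to 0.14). Glyma.19G054700, with 0 counts in infected roots, was at least 857-fold lower (adjusted p = 0.00112). The 18 libraries together called 3441 genes, 1704 higher and 1737 lower, and the fit of only these groups called 17202. Without any 1 of the 6 libraries the count was 2018 to 2128. Every library of one state lay above every library of the other in 21558 genes (50.2%, where chance gives 10%).

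Infection of KD-GmBIR1 roots called 10 higher and 78 lower genes, and the resistance locus genes were not among them. Of the 5 list genes 0 passed over all genes and 0 adjusted over the list alone (edgeR), 0 had an unadjusted p under 0.05, and 0 passed with DESeq2 or voom, with Glyma.18G022400 at 425 ± 7.16 and 449 ± 54.9 CPM and Glyma.18G022700 at 315 ± 101 and 266 ± 62.4 CPM in noninfected and infected roots (SD, n = 3). Glyma.13G118600 fell from 16.7 ± 7.7 to 0.00541 ± 0.00938 CPM (3693 and 1 counts over the group, a ratio of 3740 with an exact 95% binomial interval of 672 to 148000 that covers counting error only; adjusted p = 5.52e-08). It passed in the fit of only these groups (0.00202) and in each of its 15 alternatives (9.88e-19 to 0.0322). Glyma.10G184600 rose from 17.9 to 121 CPM (log2 fold change 2.76, SE 0.443, adjusted p = 0.0108), Glyma.17G128000 from 10.5 to 66.7 CPM (log2 fold change 2.66, SE 0.401, adjusted p = 0.00711), and Glyma.15G115300 fell from 50 to 0.247 CPM (log2 fold change -7.56, SE 0.842, adjusted p = 0.000606). These 3 did not pass in the fit of only these groups (adjusted p = 0.293, 0.129 and 0.089), Glyma.10G184600 was also lost without KD-GmBIR1 noninfected replicate 2 (0.0782) and Glyma.15G115300 with voom (0.835). Over all alternatives their adjusted p ran from 6.94e-09 to 0.293, from 1.16e-09 to 0.129 and from 1.67e-20 to 0.835. The 18 libraries called 88 genes, and the fit of only these groups called 9 (3 higher, 6 lower). The DESeq2 Wald test called 831 (251 higher, 580 lower), voom 331 (61 higher, 270 lower) and the fit without Williams 82 noninfected replicate 3 740 (162 higher, 578 lower). Libraries separated by state in 4363 genes (10.2%, where chance gives 10%). Without KD-GmBIR1 infected replicate 2 the count was 230, without infected replicate 1 it was 50 and without noninfected replicate 2 it was 52.

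**Figure D2:**
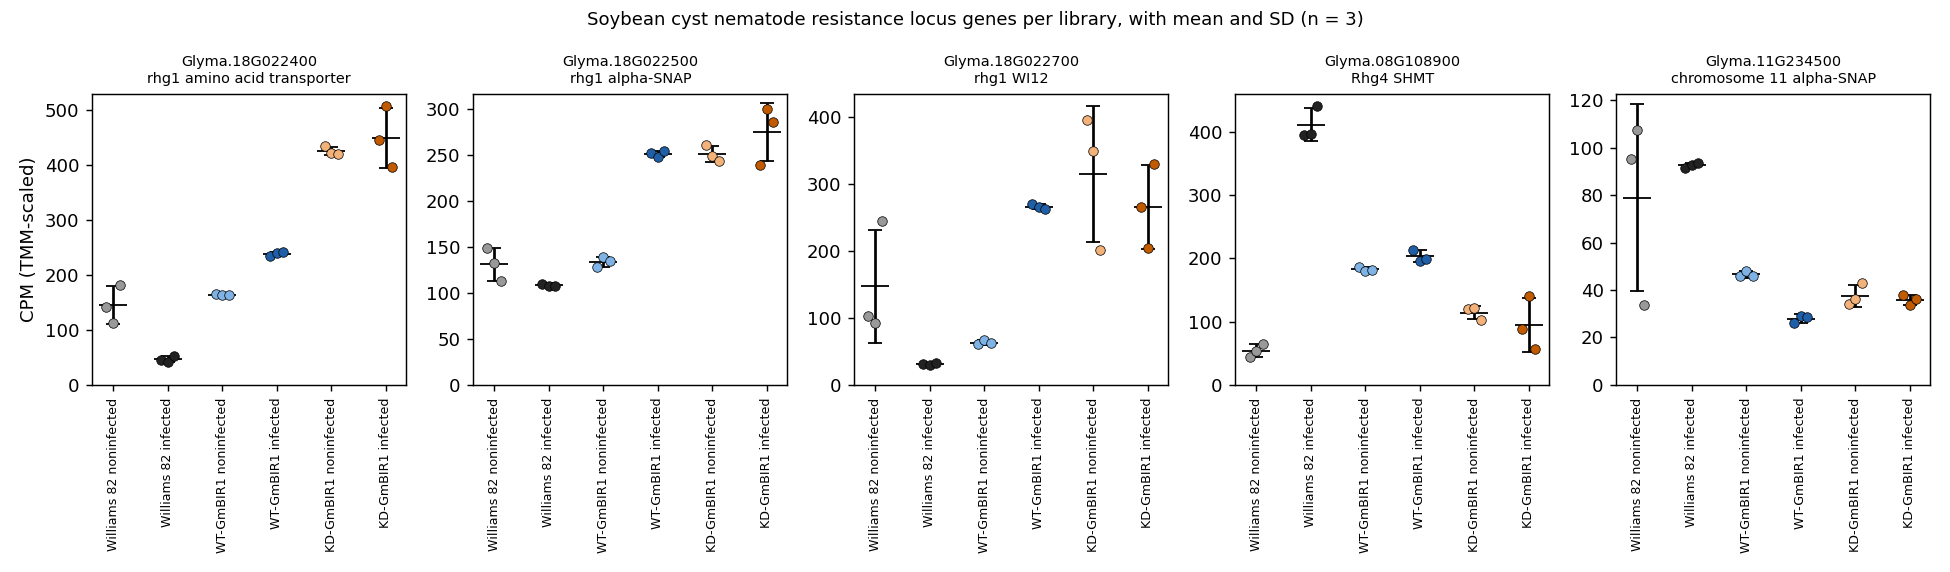
CPM (TMM-scaled) of the 5 resistance locus genes in each of the 18 libraries, by group, with the group mean and SD (n = 3). Glyma.08G108900 had a mean of 411 CPM in infected Williams 82 and 54.1 to 203 CPM in the other groups.

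The differences between infection responses were tested as interaction contrasts. The response of Glyma.18G022700 was higher in WT-GmBIR1 than in Williams 82 by 4.32 on the log2 scale (SE 0.456, edgeR adjusted p = 3.4e-06) and higher than in KD-GmBIR1 by 2.32 (SE 0.442, adjusted p = 0.00496). The difference from Williams 82 was 3.729 without Williams 82 noninfected replicate 3. The response of Glyma.08G108900 was lower than in Williams 82 in both lines, with log2 differences of -2.78 (SE 0.344, adjusted p = 1.52e-05) in WT-GmBIR1 and -3.19 (SE 0.346, adjusted p = 3.65e-06) in KD-GmBIR1. Its mean went from 54.1 to 411 CPM in Williams 82. It went from 183 to 203 CPM in WT-GmBIR1 and from 114 to 95 CPM in KD-GmBIR1, and was called in neither line. Contrasts against Williams 82 contain its noninfected group and cannot be told apart from an offset of that group. Of the 5 list genes 4, 3 and 2 were called for WT-GmBIR1 against Williams 82, KD-GmBIR1 against Williams 82 and WT-GmBIR1 against KD-GmBIR1, and 5, 3 and 2 adjusted over the list alone. These contrasts called 15225, 15990 and 1806 genes, and 14445, 11698 and 4563 in fits of only the groups compared. Without Williams 82 noninfected replicate 3 the first count was 23031, and without WT-GmBIR1 noninfected replicate 2 the last was 1203.

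Without infection, both lines had more Rhg4 transcript than Williams 82. The Williams 82 noninfected libraries stood apart from all other groups, with mean correlations of 0.763 to 0.85. Differences of the lines from them cannot be told apart from an offset of that whole group. Glyma.08G108900 was at 183 ± 2.92 CPM in WT-GmBIR1 and 114 ± 10.5 CPM in KD-GmBIR1 against 54.1 ± 10.7 CPM in Williams 82 (SD, n = 3; log2 fold changes 1.76, SE 0.246, and 1.08, SE 0.242; edgeR adjusted p = 4.1e-05 and 0.00301). In KD-GmBIR1 the transporter Glyma.18G022400 was also higher, by 1.55 on the log2 scale (SE 0.166, adjusted p = 6.51e-06). Of the list, 3 genes were called for WT-GmBIR1 and 5 for KD-GmBIR1, the same numbers adjusted over the list alone. In fits of only the groups compared, Glyma.18G022700 and Glyma.11G234500 did not pass in either line (adjusted p = 0.106 and 0.283 in WT-GmBIR1, 0.217 and 0.169 in KD-GmBIR1), nor did Glyma.18G022500 in KD-GmBIR1 (adjusted p = 0.061). These are the highest adjusted p of their alternatives, and the lowest were 0.000397 and 2.22e-07 in WT-GmBIR1 and 9.17e-06, 2.36e-08 and 1.08e-16 in KD-GmBIR1. The call of Glyma.11G234500 in WT-GmBIR1 was also lost without any 1 library other than Williams 82 noninfected replicate 3 (0.0782 to 0.201). That of Glyma.18G022700 in KD-GmBIR1 was lost without KD-GmBIR1 noninfected replicate 1 or Williams 82 noninfected replicate 1 or 2 (0.0569 to 0.0661). Glyma.18G022400 passed in WT-GmBIR1 without Williams 82 noninfected replicate 3 (0.0217, over the alternatives 0.0217 to 0.914). Glyma.U031513 was at least 488-fold higher in WT-GmBIR1 and at least 274-fold higher in KD-GmBIR1, with 0 counts in Williams 82, and neither call held with voom (adjusted p = 0.33 and 0.453, the highest of the alternatives, with the lowest at 6.56e-20 and 3.49e-17). Calls numbered 16539 for WT-GmBIR1 (7944 higher, 8595 lower) and 12852 for KD-GmBIR1 (6577 higher, 6275 lower), against 7353 and 2883 in fits of only the groups compared. Without Williams 82 noninfected replicate 3 the second count was 21711.

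In infected roots, all 5 list genes differed from Williams 82 in both lines, with the 3 Rhg1 genes higher and the other 2 lower. Glyma.18G022400 was higher by 2.35 on the log2 scale in WT-GmBIR1 (SE 0.17, edgeR adjusted p = 2.69e-07) and by 3.26 in KD-GmBIR1 (SE 0.177, adjusted p = 3.57e-09). Glyma.18G022700 was higher by 3.10 in both (SE 0.335; adjusted p = 9.44e-06 and 2.88e-06). Glyma.08G108900 was at 203 ± 9.53 CPM in WT-GmBIR1 and 95 ± 42.9 CPM in KD-GmBIR1 against 411 ± 26 CPM (SD, n = 3; adjusted p = 0.00588 and 6.65e-06). All 5 were also called adjusted over the list alone in each line. Glyma.19G086500 had 0 counts in Williams 82 and was at least 3200-fold higher in WT-GmBIR1 and at least 2120-fold higher in KD-GmBIR1. Calls numbered 9900 (5102 higher, 4798 lower) and 16330 (8736 higher, 7594 lower), and 25162 and 20340 in fits of only the groups compared.

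The calls of both lines against Williams 82 overlapped. Without infection 10500 genes were called in the same direction, 5332 higher (1220 expected from independent lists) and 5168 lower (1260 expected). Both comparisons use the same 3 Williams 82 libraries, and 12 simulations of unchanged groups against them gave a mean of 2000 shared calls. The covariance of the log2 fold changes was 4.14, against 2.62 in the simulations, and their Pearson correlation (across genes, which are not independent replicates) was 0.797, against 0.892. In infected roots 6972 genes were shared, 3711 higher (1040 expected) and 3261 lower (848 expected), with at most 1 in any simulation. There the covariance was 2.71 against 0.151 and the correlation 0.625 against 0.287. Fits of only the groups compared gave 2501 shared genes without infection and 14188 with it, and without Williams 82 noninfected replicate 3 the first was 19011. Part of the excess may come from the shared controls, since 3 libraries cannot be split into parts of 2. The simulations gave each gene 1 mean in all groups. Anything that sets a whole Williams 82 group apart enters both lists and is absent from them. Williams 82 noninfected stood apart from the other groups, with mean correlations of 0.763 to 0.85. The excess therefore does not tell a difference shared by the lines from such an offset.

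WT-GmBIR1 differed from KD-GmBIR1 at Rhg1. Without infection Glyma.18G022400, Glyma.18G022500 and Glyma.18G022700 were lower in WT-GmBIR1, by log2 fold changes of -1.38 (SE 0.165), -0.90 (SE 0.133) and -2.32 (SE 0.324), with edgeR adjusted p = 0.000205, 0.000841 and 0.000584. They were 3 of the 5 list genes, and 4 were called adjusted over the list alone. In infected roots Glyma.18G022400 was lower (log2 fold change -0.92, SE 0.163, adjusted p = 0.000802) and Glyma.08G108900 higher (1.09, SE 0.242, adjusted p = 0.00387), and the same 2 were called adjusted over the list alone. Glyma.02G205102 in noninfected roots and Glyma.03G058800 in infected roots had 0 counts in KD-GmBIR1 and were at least 549-fold and at least 1450-fold higher in WT-GmBIR1. The second call was lost with voom (adjusted p = 0.0606, the highest of the alternatives, the lowest 6.68e-06). Glyma.08G108900 without infection was at 183 ± 2.92 and 114 ± 10.5 CPM (adjusted p = 0.118, over the alternatives 0.000694 to 0.273). Calls numbered 2662 without infection (848 higher, 1814 lower) and 9827 with it (4262 higher, 5565 lower), and 9762 and 14288 in fits of only the groups compared. Without any 1 of the 6 noninfected libraries other than KD-GmBIR1 replicate 3 the first count was 1211 to 1306.

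**Figure D3:**
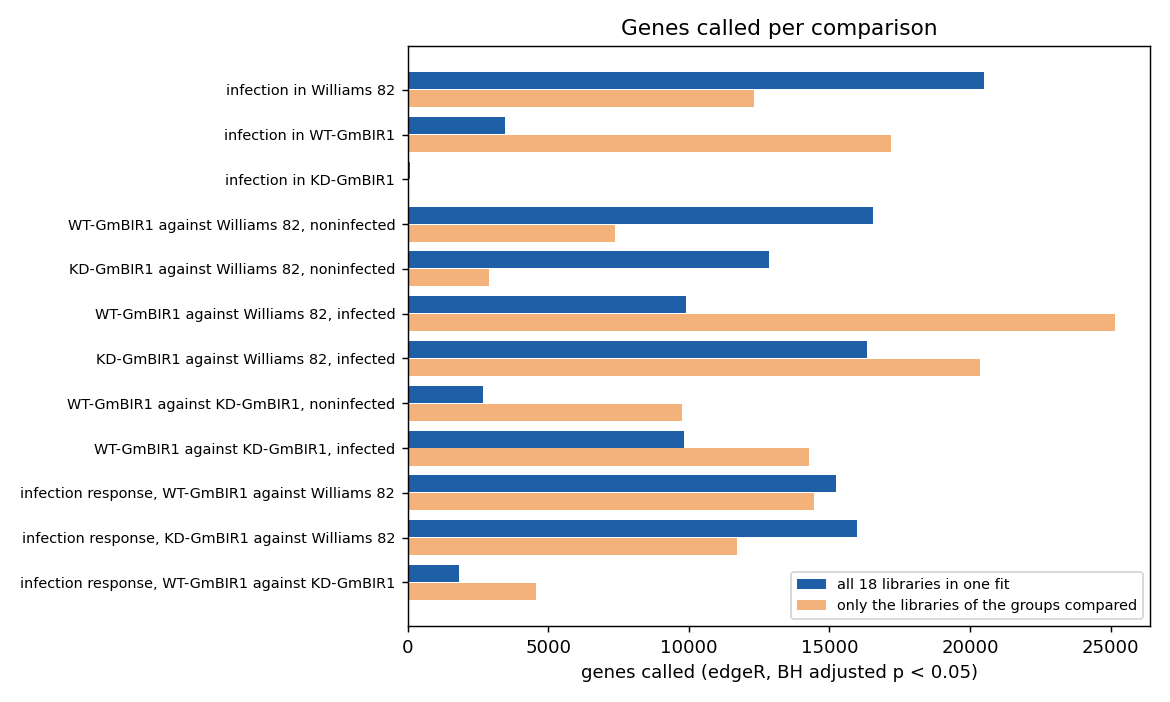
Number of genes called (edgeR, adjusted p threshold 0.05) in each of the 12 comparisons, with all 18 libraries in 1 fit (blue) and with only the libraries of the groups compared (orange). Infection in WT-GmBIR1 had 3441 and 17202 calls, and infection in KD-GmBIR1 88 and 9.

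The infection calls of the 3 genotypes were set side by side. Williams 82 and WT-GmBIR1 shared 668 higher genes (383 expected from independent lists) and 759 lower genes (439 expected), and 949 genes moved in opposite directions (821 expected). Williams 82 and KD-GmBIR1 shared 13 calls of one direction, 1 higher (2.25 expected) and 12 lower (19.7 expected), and 56 of opposite directions (20 expected). WT-GmBIR1 and KD-GmBIR1 shared 16 of one direction, 4 higher (0.397 expected) and 12 lower (3.15 expected). Another 48 genes were higher in infected WT-GmBIR1 and lower in infected KD-GmBIR1 (3.09 expected), with 0 the other way. In fits of only the groups compared, 2 of this last pair were shared and 5 were opposite (1.55 expected), while the opposite genes numbered 313 with the DESeq2 Wald test, 256 with voom and 450 without Williams 82 noninfected replicate 3. Leaving out 1 library of these groups gave 24 (KD-GmBIR1 infected replicate 1) to 94 (KD-GmBIR1 infected replicate 3) opposite and 8 (KD-GmBIR1 infected replicate 1) to 51 (KD-GmBIR1 infected replicate 2) shared genes. For Williams 82 and WT-GmBIR1 the fits of only the groups compared gave 1829 shared higher (1280 expected), 2096 shared lower (1370 expected) and 2668 opposite genes (2650 expected). For Williams 82 and KD-GmBIR1 they gave 0 shared and 4 opposite genes (1.11 expected). Without Williams 82 noninfected replicate 3, Williams 82 shared 3755 genes of one direction with WT-GmBIR1 (2365 opposite) and 139 with KD-GmBIR1. Leaving out 1 other library at a time, the lowest of these counts were 858 (WT-GmBIR1 noninfected replicate 2), 513 (WT-GmBIR1 noninfected replicate 1) and 5 (KD-GmBIR1 infected replicate 1). Across genes, which are not independent replicates, the log2 fold changes correlated at -0.0991, -0.0491 and 0.0301 for the 3 pairs of genotypes in this order.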

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

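The tests of replicate 3 as the sole cause, of swapped libraries in Williams 82 and in KD-GmBIR1 and of wrong Williams 82 labels were chosen after the results they measure had been seen. Genes called by the interaction test numbered 15225 for WT-GmBIR1 against Williams 82, 15990 for KD-GmBIR1 against Williams 82 and 1806 for WT-GmBIR1 against KD-GmBIR1. The share of false calls among them is not known, since these contrasts were not simulated. The 2 against Williams 82 contain its noninfected libraries, whose infection comparison gave 2416 false calls among 2520 in simulated data. Only 200 genes were changed there, and the share of false calls depends on that number, so it does not carry over to these counts. Of 100 splits of infection labels within the genotypes, the real one included, 1, 4 and 1 gave as many calls. The highest other counts, 13118, 16419 and 1795, came from splits that kept the real infection labels of Williams 82, Williams 82 and WT-GmBIR1, and splits that kept those of neither genotype called at most 0, 0 and 1. These splits therefore ask whether infection has an effect in either genotype and do not test a difference between the responses, for which they neither exclude chance nor show it.

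For WT-GmBIR1 against Williams 82 the fitted log2 differences were 2.17 for Glyma.18G022400, 1.18 for Glyma.18G022500, 4.32 for Glyma.18G022700 and -2.78 for Glyma.08G108900. Glyma.09G162700, Glyma.16G212200, Glyma.18G270051 and Glyma.08G175400 had fitted values of 25.56, 24.36, -24.06 and -19.42. For KD-GmBIR1 against Williams 82 the values were 1.71 for Glyma.18G022400, 2.00 for Glyma.18G022700 and -3.19 for Glyma.08G108900, and 25.68, 23.59, -16.92 and -14.02 for Glyma.09G162700, Glyma.09G163000, Glyma.03G032500 and Glyma.03G058800. For WT-GmBIR1 against KD-GmBIR1 they were 0.77 for Glyma.18G022500 and 2.32 for Glyma.18G022700, and 16.09, 13.43, -18.79 and -15.22 for Glyma.03G058800, Glyma.05G165700, Glyma.02G205102 and Glyma.18G186501. Fitted values beyond 10 on this scale come from groups at or near 0 counts, depend on the prior count and bound nothing. Calls were lost without KD-GmBIR1 infected replicate 2 for Glyma.02G205102 and Glyma.18G186501 between the lines, and without KD-GmBIR1 infected replicate 1 for Glyma.09G163000 (adjusted p = 1, edgeR, the highest of their alternatives, the lowest 3.27e-21, 3.51e-11 and 6.3e-27). Between the lines the call of Glyma.18G022500 was lost without any 1 of 7 libraries (0.0542 to 0.0879, over all alternatives 1.59e-06 to 0.0879). That of Glyma.03G058800 was lost with voom (0.105) and without WT-GmBIR1 noninfected replicate 1 (0.0505) or 3 (0.05), over all alternatives 1.07e-05 to 0.105. For WT-GmBIR1 against Williams 82 the call of Glyma.08G175400 was lost with voom (0.0942, over all alternatives 2.68e-45 to 0.0942).

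Among alignments outside the gene counts, Williams 82 noninfected replicate 3 held 68.7% non-unique alignments, against 2.82% to 5.66% in the other libraries. Of the genes with 0 counts in the other 17 libraries, 3176 (59.7%) were detected there, against 5 to 29 such genes for any other library.

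The Williams 82 noninfected libraries stand apart from the other groups. Without replicate 3, 26345 genes were called by infection in Williams 82, more than the 20511 with it. Calls also rose in comparisons that do not use this library, so that rise cannot decide whether replicate 3 is the sole cause. Replicates 1 and 2 correlated with the other groups at means of 0.776 to 0.867, against 0.859 to 0.964 among those groups. On the first principal component they lay at 358.6 and 420.2, and no other library lay above 78.05. These values argue against replicate 3 as the sole cause. A swap of 1 or 2 libraries with the infected group is argued against too, since 0 infected libraries correlated better with the noninfected group than with their own. An exchange of whole groups would leave these correlations as they are. Such an exchange, other wrong labels, another tissue or another growth condition of the whole group cannot be told apart from a noninfected state particular to Williams 82. Markers could not be read for this, since 0 IDs carry names. A noninfected state that acts alike in all genotypes is argued against. The noninfected lines correlated with their own infected groups at means of 0.941 (WT-GmBIR1) and 0.964 (KD-GmBIR1). With Williams 82 noninfected they correlated at 0.807 and 0.847. A noninfected state particular to Williams 82 as the biological cause was not tested apart from the explanations left open.

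Infection called 88 genes in KD-GmBIR1 and 3441 in WT-GmBIR1. A larger spread with an equal effect is argued against: the variance of the infection effect, from products of fold changes that share no library, had a mean of 0.0507 (log2 squared) in KD-GmBIR1, 1.15 in WT-GmBIR1 and 3.77 in Williams 82, and single products in KD-GmBIR1 ran from -0.127 to 0.274. A swap of 1 or 2 libraries between the KD-GmBIR1 groups is argued against, since the other 9 splits of these 6 libraries, which undo each such swap, called at most 13 genes. An exchange of the whole groups would turn the directions and leave the number of calls as it is, so it would not account for that number. A single wrong label, with the effect of WT-GmBIR1 in the other libraries, is argued against. Each pairing would still hold a product without that library, yet no product exceeded 0.274, against at least 1.12 in WT-GmBIR1. The same products argue against a lack of infection in replicate 2 alone, with the effect of WT-GmBIR1 in the other libraries. Uneven infection of more than 1 library stays open. Infected replicate 2 correlated at 0.975 with the noninfected group and 0.96 with its own (replicate 1 at 0.964 with each). A smaller response of this line, with or without a wrong label, also stays open. It may be biological and was not tested apart from uneven infection.

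For comparisons of 3 against 3 libraries the 10 splits cannot give a share under 0.1, and in each of the 9 the real split, 1 of 10, gave the most calls. The highest other counts were 0 for infection in Williams 82, for infection in WT-GmBIR1, for both lines against Williams 82 infected and for WT-GmBIR1 against KD-GmBIR1 in either state. They were 13 for infection in KD-GmBIR1, and 615 and 3724 for WT-GmBIR1 and KD-GmBIR1 against Williams 82 noninfected.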

How the results depend on the processing

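The fits with voom, without Williams 82 noninfected replicate 3 in the shared spread and with divided counts were added after seeing the data. Over all alternatives 230 counts of calls stayed within 1.5 times their value and 100 did not. Of the values of named genes 1619 kept direction and side of the threshold, 60 lost the call, 33 gained it and 16 changed sign. Size factors of DESeq2 and no filter on low counts moved no count of calls by over 1.5 times. DESeq2 gave no adjusted p for some named genes, which have no value there. The groups differ in spread (biological coefficient of variation 0.176 to 1.14). Counts moved in the fit of only the groups compared, which takes its spread from those groups alone. Counts moved with voom too, which scales a shared spread per gene by a weight for each group. They also moved with the DESeq2 Wald test, without Williams 82 noninfected replicate 3 in the fit and on leaving out 1 library. The cause of the moves was not tested.

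With the DESeq2 Wald test the calls numbered 5681 for infection in WT-GmBIR1, 831 for infection in KD-GmBIR1, 5003 for WT-GmBIR1 against KD-GmBIR1 noninfected and 3602 for the difference of their infection responses. Infection calls shared in 1 direction were 2248 for Williams 82 and WT-GmBIR1, 122 for Williams 82 and KD-GmBIR1 and 109 for WT-GmBIR1 and KD-GmBIR1. Opposite calls were 313 for the lines and 1648 for Williams 82 and WT-GmBIR1.

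With only the groups compared in the fit, infection called 12305 genes in Williams 82, 17202 in WT-GmBIR1 and 9 in KD-GmBIR1. Against Williams 82 noninfected the counts were 7353 for WT-GmBIR1 and 2883 for KD-GmBIR1, and WT-GmBIR1 against Williams 82 infected had 25162. WT-GmBIR1 against KD-GmBIR1 noninfected had 9762, and the difference of their infection responses 4563. Shared infection calls were 3925, 0 and 2 for Williams 82 with WT-GmBIR1, Williams 82 with KD-GmBIR1 and the lines, and opposite calls 5 for the lines and 2668 for Williams 82 and WT-GmBIR1. Shared calls of the lines against Williams 82 were 2501 noninfected and 14188 infected.

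With voom and group weights, infection called 13440, 17643 and 331 genes in Williams 82, WT-GmBIR1 and KD-GmBIR1. Against Williams 82 noninfected the counts were 8860 for WT-GmBIR1 and 5132 for KD-GmBIR1, and WT-GmBIR1 against Williams 82 infected had 26938. WT-GmBIR1 against KD-GmBIR1 had 11131 noninfected, 15434 infected and 5228 for the difference of responses. Shared infection calls were 4229 for Williams 82 and WT-GmBIR1 and 43 for the lines, and opposite calls 256 for the lines and 2547 for Williams 82 and WT-GmBIR1. Shared calls of the lines against Williams 82 were 4324 noninfected and 15118 infected.

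With Williams 82 noninfected replicate 3 left out of the fit, infection called 7997 genes in WT-GmBIR1 and 740 in KD-GmBIR1, and WT-GmBIR1 against Williams 82 infected had 16583. WT-GmBIR1 against KD-GmBIR1 had 8188 noninfected, 16675 infected and 4937 for the difference of responses. The lines shared 92 infection calls, 450 were opposite, and 11639 calls against Williams 82 infected were shared. Dividing counts by the modal low count gave 82 opposite calls between the lines by the first definition and 76 by the second, against 48.

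Leaving out 1 library at a time gave 2018 to 2128 calls for infection in WT-GmBIR1, 50 to 230 in KD-GmBIR1, 10097 to 21711 for KD-GmBIR1 against Williams 82 noninfected and 1211 to 3224 for WT-GmBIR1 against KD-GmBIR1 noninfected. The differences of infection responses ranged from 12721 to 23031 for WT-GmBIR1 against Williams 82 and from 1203 to 1812 between the lines. Shared infection calls ranged from 858 to 3755 for Williams 82 and WT-GmBIR1, 5 to 139 for Williams 82 and KD-GmBIR1 and 8 to 51 for the lines. Opposite calls ranged from 24 to 94 for the lines and 513 to 2365 for Williams 82 and WT-GmBIR1, and shared calls against Williams 82 noninfected from 8347 to 19011. A smaller number of libraries per group is part of each of these fits.

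The replicate numbers did not pair the libraries. Over 15 pairs of groups, the deviations of libraries with the same number correlated at -0.098 to 0.091, and in 0 pairs did every library correlate best with its own number. The fit with a replicate block called 19760 genes for infection in Williams 82, 3156 in WT-GmBIR1 and 69 in KD-GmBIR1, and moved no count of calls by over 1.5 times. It ended the call of Glyma.11G234500 for WT-GmBIR1 against Williams 82 noninfected (edgeR adjusted p = 0.0583, over all alternatives 2.22e-07 to 0.283). Under it the log2 fold change of Glyma.18G022700 for WT-GmBIR1 against KD-GmBIR1 infected was 0.02077.

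Each change of sign was in a list gene that was not called, under the alternative or before. For Glyma.18G022700 in WT-GmBIR1 against KD-GmBIR1 infected, at -0.000472 on the log2 scale, the values were 0.0519 with DESeq2 size factors, 0.05189 with the Wald test, 0.01203 with only the groups compared, 0.0348 with voom and 0.04337 and 0.05152 with divided counts. It was 0.0756 and 0.08073 without WT-GmBIR1 infected replicate 2 or 3, and leaving out 1 library gave -0.1493 (KD-GmBIR1 infected replicate 2) to 0.1628 (KD-GmBIR1 infected replicate 3). For infection in KD-GmBIR1, leaving out 1 library gave -0.01532 (infected replicate 2) to 0.1679 (infected replicate 3) for Glyma.18G022400, -0.6696 (infected replicate 2) to 0.00503 (infected replicate 3) for Glyma.08G108900 and -0.1276 (noninfected replicate 1) to 0.03733 (noninfected replicate 3) for Glyma.11G234500. For Glyma.11G234500 it gave -0.129 to 0.5074 by infection in Williams 82 and -0.5757 to 0.06546 for the response in KD-GmBIR1 against Williams 82, and for Glyma.18G022500 in WT-GmBIR1 against Williams 82 noninfected -0.06215 to 0.1447. In these 3 the sign changed without Williams 82 noninfected replicate 3.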

Other observations

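Both tests of the low counts were chosen after the low counts had been seen, and dividing counts by the modal low count was added after seeing the data. Even numbers were favoured among low counts in 17 of the 18 libraries. Counts from 4 to 40 were even in 63.5% to 88.9% of genes, where no preference gives 51.4%, and in Williams 82 noninfected replicate 3 in 53.3%. A count minimum set before deposit is argued against as the whole cause, since it leaves no preference for even counts above it and the lowest share was 63.5%. Repeated counting of each molecule may contribute: between replicates of Williams 82 infected, genes with a mean of 5 to 20 counts had a median variance to mean ratio of 7.31, where single counts give 1, although biological spread raises this ratio too. Dividing counts by the modal low count gave 4683 or 4619 calls for infection in WT-GmBIR1, by the first (smoothed) or second (most common even count) definition, against 3441.

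Genes called by infection in WT-GmBIR1 lay next to each other in ID order more often than in random orders. Of 3422 called genes on numbered chromosomes, 320 adjacent pairs moved in the same direction, against a mean of 136.5 and at most 179 in 10000 random orders (ratio 2.34). The number lay above every random order in each of the 9 comparisons of 2 groups. The ratio was 1.16 for infection in Williams 82 and 2.2 for WT-GmBIR1 against KD-GmBIR1 without infection. It was highest for infection in KD-GmBIR1, at 35.7, from 5 pairs against a mean of 0.1399. Gene families and reads shared between neighbouring copies were not tested.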
